A study of Coilia nasus with 12 samples.

How the data were processed

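RNA was sequenced from the stomachs of 12 individual Coilia nasus, 6 labelled food intake and 6 labelled no food intake. The labels give stomach as tissue and gastric mucosa as source. Per the labels' protocols the RNA was extracted with TRIzol, made into 12 libraries and sequenced in pairs on an Illumina HiSeq instrument. Reads were trimmed with cutadapt and checked with FastQC, per the submitters' processing notes, which give no versions. The transcripts were assembled without a genome, as the Trinity identifiers in the deposited table show. The values that the authors deposited were read as TPM per unigene and library, from their column totals, since the file header names no unit. The quantifier and any filter on unigenes are not given in the sources used here. Depth is not recorded by TPM, so the precision of a single value is known only from the spread between fish.

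All 12 sample columns were matched to the labels (0 unmatched). The test planned first was for counts, and because the table holds TPM the plan's test for TPM was used: limma (3.58.1) with a trend in the prior variance, on log2(TPM + 1), for unigenes at 1 TPM or more in at least 6 libraries, with group as the only term. Adjusted p is by Benjamini and Hochberg, with a threshold of 0.05, and direction is food intake over no food intake. R 4.3.3 (with the data.table package, version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used. On simulated data with 40142 unigenes, limma recovered 3 of 100 unigenes changed by 1 log2 unit and 53 of 100 changed by 2. Both sizes were in the same simulated set, which gave 3 false calls in total. It recovered 200 of 200 changed by 2 log2 units when these were drawn from those with the smallest spread, with 14 false calls.

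The genes named by single test were the 12 higher and 12 lower with the smallest p among named unigenes with an absolute log2 fold change of at least 1 and a mean of at least 1 TPM, 1 unigene per gene name. The rule asked first for adjusted p under 0.05 and filled up by unadjusted p, which is how all 24 were taken. A pair of genes that met the rules for naming, 1 of them among the 24, is not reported here. For each list, up to 4 members with the smallest p could be named, with the 2 most abundant members for lists of other tissues and cell types. Members of the gastric and appetite lists could be named whatever their p. Gene names are those of the deposited annotation, and the best protein match is given for named genes where it is another gene or a mammalian protein.

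The 30 gene lists were written before the data were examined and matched by gene symbol, or by a pattern of symbols for ribosomal proteins, oxidative phosphorylation and ion transport. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation, fry and an exact permutation of the mean score per library over the 462 splits beside it. List adjusted p values in the text are from camera unless another test is named. In a simulation with 1 list raised by 1 log2 unit, camera gave that list an adjusted p of 5.48e-29 and called 0 others. The simulated unigenes were drawn independently, whereas the estimated correlation was 0.567 in the gastric acid list. That simulation therefore cannot show how often camera calls lists of correlated members without a true change. Library measures and distances were compared by exact permutation. Unigenes detected in 1 group only were those above 0 in all 6 libraries of that group and at 0 in the other 6.

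The rRNA-like unigenes were those with a mean of at least 1000 TPM whose log values correlated at 0.95 or more with the unigene named ART2. Library batches were read from mitochondrial unigenes with a chicken best match and are not given by the labels. Alternatives set before the data were examined were quantile normalization, limma without trend, no filter, a minimum of 5 TPM, a pseudocount of 0.1, a replicate block, values summed by gene name, 1 unigene per gene name, estimated correlation, other detection limits, other distances and each library left out. Alternatives added after seeing the data were the batch as a term, each batch alone, rescaling without the rRNA-like unigenes, median of ratios scaling, array weights, a robust prior variance, annotated unigenes alone, removal of batch-differing unigenes, omission of food intake 6 with no food intake 3, and permuted list scores. The real split and others drawn with a fixed seed made up 100 splits of the 12 libraries.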

Results

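The stomachs of 12 individual Coilia nasus, an estuarine anchovy, were profiled by RNA sequencing. The labels name the tissue as stomach and the source as gastric mucosa, so whether the muscle layer was included is open. The labels place 6 fish under food intake and 6 under no food intake, and the comparison asks how gene expression in the stomach differs between fish that had taken food and fish that had not. The expression table held 63567 unigenes assembled without a reference genome, of which 18158 carried a gene name. The deposited values were read as TPM because the columns had near-equal totals of 984119 to 992092, as that unit gives. TPM keeps no record of depth, so the number of reads behind each value is unknown. Each library had between 49867 and 57025 unigenes above 0, and 40142 unigenes reached 1 TPM in at least 6 libraries and were tested. Group values below are mean TPM ± SD with n = 6 per group, and fold changes are food intake over no food intake on the log2(TPM + 1) scale, which understates changes at low TPM.

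The transcriptomes carried the signature products of the stomach. The most abundant CHIA unigene, an acidic chitinase that digests chitin, stood at 104140 ± 38182 TPM with food intake and 105560 ± 52085 without. The highest PGA unigene, a pepsinogen, had 38806 ± 17830 against 18127 ± 17955 TPM, and the highest PGC unigene, the precursor of gastricsin, had 31920 ± 16452 against 20074 ± 8702 TPM. The top unigene named MUC5AC, a secreted mucin whose best match was mucin-5B-like, had 3605 ± 2270 against 1960 ± 852 TPM. The alpha subunit of the gastric proton pump, atp4a, had 490.1 ± 205 against 310 ± 181 TPM in its most abundant unigene. None of these differences passed the test over all unigenes.

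Libraries did not separate by feeding group. The mean Euclidean distance was 206.2 within groups and 208.5 between groups (two-sided exact permutation over the 462 splits, p = 0.506), and Spearman correlations between libraries ranged from 0.469 to 0.695. The first principal component took 18.4% of the variance and set food intake 6 apart. In that library, 7 unigenes that tracked, across libraries, a unigene matching an rRNA-antisense open reading frame (called rRNA-like here) took 64.2% of the TPM, against 4.34% to 16.4% in the other food intake libraries and 6.12% to 26.9% in the no food intake libraries. The group means of this share were 20.47 ± 22.02% and 15.02 ± 9.46% (two-sided exact permutation p = 0.747). Mitochondrial unigenes of the fish had 23410 ± 7341 TPM with food intake and 23720 ± 7658 TPM without (two-sided exact permutation p = 0.946).

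**Figure D1:**
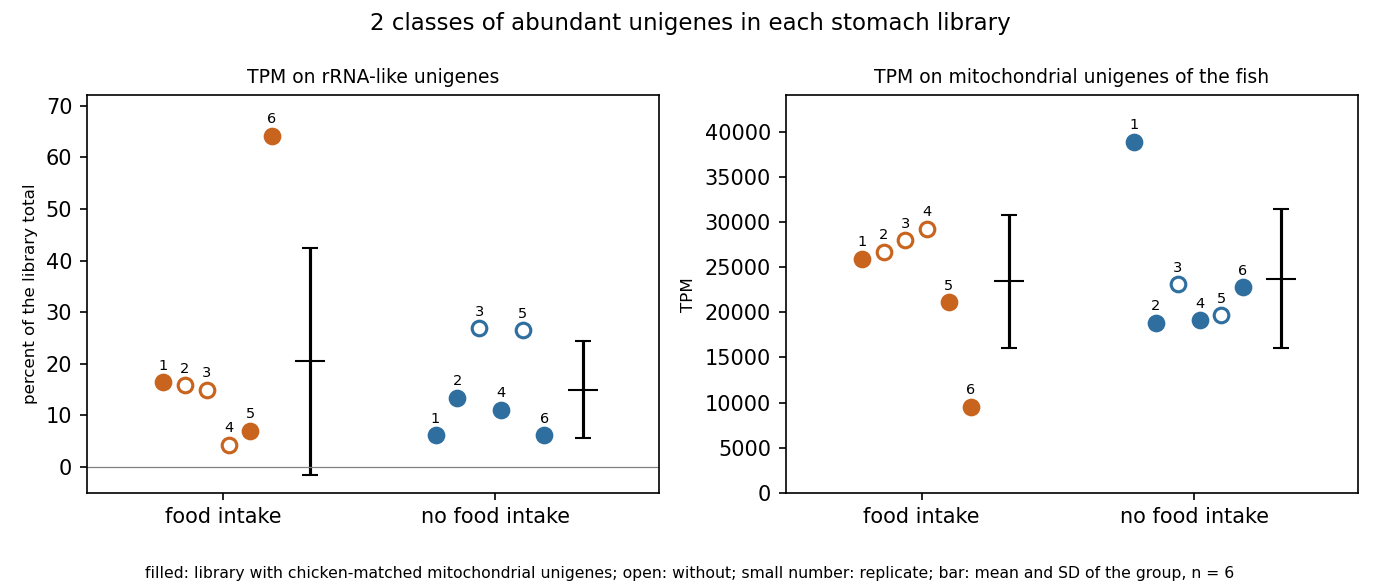
Share of each library's TPM on the 7 rRNA-like unigenes (left, percent) and TPM on mitochondrial unigenes of the fish (right). Points are the 12 libraries numbered by replicate, filled where chicken-matched mitochondrial unigenes were above 0; bars give the mean and SD of each group (n = 6); food intake 6 lies at 64.2% on the left and at 9526 TPM, the lowest value, on the right.

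Unigenes matching other organisms split the libraries into sets that cross the feeding groups. The 9 unigenes with a chicken mitochondrial best match were above 0 in 7 libraries (food intake 1, 5 and 6, and no food intake 1, 2, 4 and 6), at 31.05 to 97.2 TPM, and at 0 in the other 5. In the same 7 libraries the 23 human-matched mitochondrial unigenes had 1378 to 2514 TPM, against 38.0 to 67.5 TPM in the other 5. Between the sets, 787 of the 40142 tested unigenes differed by limma at adjusted p under 0.05, with 707 higher in the 7 libraries. Unigenes matching other organisms were not removed before this test. Part of the count can therefore follow from how the sets were defined, and it is not a count of fish genes alone. These sets were treated as library batches, with 3 food intake against 4 no food intake libraries in the first and 3 against 2 in the second, and within-batch values are given in that order.

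The single genes with the smallest unadjusted p had varied functions and share no tested theme. On the side higher with food intake, GUCA2A (guanylin, a peptide that regulates salt and water secretion in the gut; unigene TRINITY_DN31520_c0_g1) had 81.9 ± 41.0 TPM with food intake and 22.9 ± 11.1 without, a log2 fold change of 1.79 (SE 0.46), and lay above the no food intake median in 6 of 6 food intake libraries. AQP4, a water channel, had 11.7 ± 8.99 against 2.52 ± 1.94 TPM (log2 1.71, SE 0.50). B3GALT2, a galactosyltransferase, had 19.98 ± 23.2 against 0.827 ± 1.06 TPM (log2 2.59, SE 0.73). The unigene named LYVE1, whose best match was a CD44-like receptor, had 12.7 ± 16.2 against 0.658 ± 0.746 TPM. The remaining genes named on the higher side were cmpk (log2 2.02), EF2 (1.54), DHX30 (1.44), TDH (1.40), PCDH12 (1.36), RAB8A (1.22) and Tjap1 (1.17). Of these, EF2, DHX30, PCDH12 and Tjap1 were short unigenes of 205 to 291 bases, with means of 0.453 to 0.975 TPM without food intake.

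On the side lower with food intake, eif4ebp3l, which binds the cap-binding factor eIF4E and restrains translation, had 11.6 ± 3.88 TPM with food intake and 33.7 ± 19.3 without (log2 -1.33, SE 0.37). sesn1, a sestrin that restrains mTORC1 when amino acids are scarce, had 4.68 ± 2.15 against 17.4 ± 15.2 TPM (log2 -1.47, SE 0.41). ACAC, acetyl-CoA carboxylase, had 0.677 ± 0.477 against 4.05 ± 2.55 TPM (log2 -1.48, SE 0.36), and SLC1A3, a glutamate transporter, had 4.88 ± 3.68 against 13.3 ± 5.36 TPM (log2 -1.42, SE 0.39). sptssb, a small subunit of serine palmitoyltransferase, had 32.9 ± 13.6 against 84.9 ± 38.8 TPM (log2 -1.32). The transcription factor KLF11 (log2 -1.47), the histone methyltransferase EZH1 (-1.46), Gldn (-1.39), UBE2E3 (-1.29, best match in the mouse), TMEM121 (-1.27) and Tmem67 (-1.24) were also named, as was a unigene named plk4 (-1.33) whose best match was instead an apolipoprotein L6-like protein. Gldn, Tmem67 and UBE2E3 were short unigenes of 204, 229 and 299 bases. All 24 genes that met the naming rule had the same sign within each batch, with the batch as a term and after the rRNA-like unigenes were removed and TPM rescaled, which their choice over the same 12 libraries largely fixes and which adds no evidence.

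None of the 24 passed the test over all unigenes (limma, smallest adjusted p = 0.768), so they were taken by unadjusted p. limma called 0 unigenes higher and 0 lower at adjusted p under 0.05. At unadjusted p under 0.05 it had 997 higher and 1521 lower, where 2007 are expected by chance, and with the rRNA-like unigenes removed and TPM rescaled the split turned to 2279 higher and 1014 lower. That rescaling moved the median log2 change over all tested unigenes from -0.04 to 0.06. The smallest adjusted p, 0.0749, belonged to a pair of short unigenes without annotation, TRINITY_DN26717_c0_g1 (209 bases, log2 2.09) and TRINITY_DN26246_c2_g1 (216 bases, log2 -2.28), named here after their values were seen. limma without the trend also called 0, quantile normalization called that pair, and array weights called TRINITY_DN26717_c0_g1 alone.

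Of 30 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 placed 8 higher and 1 lower with food intake at adjusted p under 0.05. None of the 9 calls held with an estimated correlation (smallest adjusted p = 0.741 with an estimated correlation, which is also the value of each of the 9). fry called 0 lists (smallest adjusted p = 0.723), and exact permutation of each list's mean score per library called 0 (smallest adjusted p = 0.775). No list had a member past the threshold over all unigenes. Adjusted over the list alone, the count was 1, SLC1A3 in the peptide and amino acid transport list (adjusted p = 0.0377). The series description names feeding, appetite, digestion and energy metabolism as themes of these same libraries, so the lists on those themes are not independent evidence of their direction.

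Gastric acid secretion had 18 of 22 unigenes higher with food intake and a median log2 change of 0.85 (camera adjusted p = 3.99e-06; adjusted p = 0.741 with an estimated correlation). At unadjusted p under 0.05, 5 were higher and 0 lower. kcnq1, a potassium channel of the acid-secreting cell, had 5.62 ± 2.78 against 1.955 ± 1.21 TPM (log2 1.16), EZR, the membrane linker ezrin, had 16.8 ± 13.3 against 4.13 ± 2.59 TPM (log2 1.56), and ca2, a carbonic anhydrase (best match carbonic anhydrase 1-like), had 32.7 ± 20.9 against 10.7 ± 4.94 TPM (log2 1.28). A second atp4a unigene had 383.7 ± 244 against 172 ± 111 TPM (log2 1.43), whereas the histamine receptor Hrh2 had 14.7 ± 5.01 against 18.8 ± 9.76 TPM. The list median was 0.17 and 1.39 within the batches (camera adjusted p = 0.0533 and 2.07e-05), where smooth muscle genes had medians of 0.42 and -0.37 and matrix genes 0.58 and -0.74, and it was 1.02 after rescaling. In the second batch the mean acid score was 2.14 in no food intake 3 and 4.47 in no food intake 5. Its food intake libraries had 4.33 to 5.12, so the difference there rests largely on no food intake 3. With 1 unigene per gene name, 8 of 12 genes were higher (median 0.37, camera adjusted p = 0.0313; adjusted p = 0.778 with an estimated correlation). The medians of these 12 genes had opposite signs within the batches, -0.10 and 1.41. Over all 22 unigenes the median was 0.42 without no food intake 3. With no filter it was 0.53 over 26 unigenes.

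Gastric digestive enzymes had 16 of 20 unigenes higher, with a median of 0.37 (camera adjusted p = 0.0392; adjusted p = 0.741 with an estimated correlation). The 20 unigenes carried only 3 gene names (CHIA, PGA and PGC). With 1 unigene per gene name the list fell under the minimum of 5 members and was not tested. The medians within the batches had opposite signs, -0.41 and 1.58. In the second batch the mean score was 8.21 and 9.91 in no food intake 3 and 5, and 10.39 to 10.62 with food intake. The highest PGA unigene (log2 1.41) lay above the no food intake median in 6 of 6 food intake libraries, but abundant PGA unigenes did not share a direction. Another had 10878 ± 4263 against 14663 ± 8744 TPM (log2 -0.10) and lay below that median in 6 of 6. A further PGA unigene (log2 0.21) lay above it in 3 of 6. Of the 20 unigenes, 1 was higher at unadjusted p under 0.05. The call was lost without food intake 2, 3, 4 or 5 and without no food intake 3 or 4, with camera adjusted p up to 0.669, with a pseudocount of 0.1 (0.0778), with array weights (0.071), without food intake 6 and no food intake 3 together (0.24) and without the batch-differing unigenes (0.0503). The median was 0.20 without food intake 5, 0.58 without food intake 6 and 0.04 without no food intake 3. In the mucous surface epithelium list 18 of 21 unigenes were higher (median 0.42, camera adjusted p = 0.0508, and 0.741 with an estimated correlation). At the preset correlation, camera called it with the batch as a term (adjusted p = 0.0105) and after rescaling (adjusted p = 0.0241). A unigene named FCGBP, a mucus-associated protein, with an uncharacterized best match, had 178 ± 373 against 508 ± 486 TPM (log2 -3.18). It was not the most abundant FCGBP unigene. With the most abundant unigene per gene name, the lowest log2 change in the mucous list was -0.59, and 0 of 11 genes were lower at unadjusted p under 0.05.

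Genes of the mitochondrial citric acid cycle were higher in number with food intake. In the TCA cycle and pyruvate dehydrogenase list 39 of 45 unigenes were higher, with a median of 0.43 (camera adjusted p = 4.15e-06; adjusted p = 0.741 with an estimated correlation) and medians of 0.31 and 0.53 within the batches. The median was 0.28 without food intake 1 and 0.68 without food intake 6. SUCLA2, a succinyl-CoA ligase subunit, had 10.7 ± 5.62 against 4.67 ± 1.56 TPM (log2 0.88). Oxidative phosphorylation had 81 of 114 unigenes higher (median 0.11, camera adjusted p = 0.01; adjusted p = 0.741 with an estimated correlation). Its medians within the batches were -0.10 and 0.38, and the call was lost without food intake 3 or no food intake 6 (adjusted p up to 0.201) and with 1 unigene per gene name (0.068). The median turned to -0.02 without food intake 3, and it was 0.07, 0.18 and 0.38 without food intake 2, 4 or 6 and 0.175 without no food intake 2. After rescaling it was 0.26. A unigene of CYC1, cytochrome c1, had 18.9 ± 13.8 against 5.29 ± 2.12 TPM. It was not the most abundant CYC1 unigene. With the most abundant unigene per gene name, 0 of 75 genes were higher at unadjusted p under 0.05.

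Fatty acid synthesis had 22 of 32 unigenes higher (median 0.23, camera adjusted p = 0.00531; adjusted p = 0.741 with an estimated correlation), with within-batch medians of 0.33 and 0.42 (camera adjusted p = 0.00248 and 0.149) and medians of 0.14 without food intake 1 and 0.42 without food intake 6. Its leading members had opposite signs. fads2, a fatty acid desaturase, had 5.00 ± 5.56 against 1.05 ± 1.22 TPM (log2 1.22) and Acly, ATP-citrate lyase, had a log2 change of 0.85, while ACACB, an acetyl-CoA carboxylase, had 4.03 ± 2.23 against 8.23 ± 4.12 TPM (log2 -0.89). The unigene named ACAC, also an acetyl-CoA carboxylase and lower with food intake (log2 -1.48), was not matched to the list, so its counts leave it out. Cholesterol synthesis had 12 of 15 unigenes higher (median 0.26, camera adjusted p = 0.0313; adjusted p = 0.741 with an estimated correlation), with medians of 0.22 and 0.39 within the batches and 0 members at unadjusted p under 0.05. That call was lost without food intake 2, 3 or 5 and without no food intake 1 or 6 (adjusted p up to 0.0828), with 1 unigene per gene name (0.0669) and with a pseudocount of 0.1 (0.0753), and the median was 0.42 without food intake 6. With no filter the cholesterol synthesis median was 0.43. Glycolysis had 21 of 35 unigenes higher (adjusted p = 0.159) and fatty acid oxidation 24 of 38 (adjusted p = 0.314). Within glycolysis a unigene of PFKM, muscle phosphofructokinase, had 0.438 ± 0.378 against 3.53 ± 4.38 TPM (log2 -1.31), and Pgk1 had 13.4 ± 10.8 against 5.28 ± 1.41 TPM (log2 0.89). That PFKM unigene was not the most abundant of its name. With the most abundant unigene per gene name, the lowest log2 change in glycolysis was -0.69, and 0 of 18 genes were lower at unadjusted p under 0.05.

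The heat shock and unfolded protein response list had 41 of 65 unigenes higher and a median of 0.35 (camera adjusted p = 0.000191; adjusted p = 0.741 with an estimated correlation). At unadjusted p under 0.05, 13 were higher and 1 lower, and the medians within the batches were 0.36 and 0.40 (camera adjusted p = 3.07e-06 and 0.188). The median was 0.21, 0.22 and 0.53 without food intake 1, 5 or 6, 0.12 with no filter and 0.65 with 1 unigene per gene name. The members with the smallest p were proteins of the endoplasmic reticulum: MANF, a stress-induced secreted factor, had 14.9 ± 14.1 against 2.13 ± 1.35 TPM (log2 1.89), SDF2L1, a cofactor of the chaperone BiP, had 15.1 ± 13.8 against 2.55 ± 1.57 TPM (log2 1.70), and hyou1, an ER chaperone, had 8.99 ± 11.8 against 1.06 ± 0.744 TPM (log2 1.61). A unigene of the cytosolic chaperone HSP90AB1 had 334 ± 229 against 745 ± 381 TPM (log2 -1.28). It was not the most abundant HSP90AB1 unigene. With the most abundant unigene per gene name, 0 of 27 genes were lower at unadjusted p under 0.05, and the lowest log2 change was -0.81.

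Ribosomal protein transcripts were abundant, and most ribosomal protein genes had a lower mean with food intake, although 0 of them passed limma's test over all unigenes or adjusted over the list alone. Over all 294 unigenes of the list the median was -0.05 and camera gave adjusted p = 0.102. That value depended on the setting: camera adjusted p was 0.979 with the batch as a term (median 0.12) and from 0.00267 to 0.932 with 1 library left out, under 0.05 and lower without food intake 1, 4 or 6 and without no food intake 3 or 4. With 1 unigene per gene name, an alternative fixed before the data were examined, 81 of 99 genes were lower, 48 of them at unadjusted p under 0.05, and the median was -0.98 (camera adjusted p = 1.2e-17; adjusted p = 0.778 with an estimated correlation). The 99 had a median mean of 873 TPM. The other 195 unigenes of the list had 1.97 TPM, a median log2 change of 0.05 and 2 lower at unadjusted p under 0.05. The name pattern also caught 10 genes for S6 kinases and an RPS19-binding protein (median 0.205), and of the 89 ribosomal protein genes proper 77 were lower. RPS16 (best match in a camel) had 557 ± 216 against 1336 ± 460 TPM (log2 -1.31), RPS3 had 978 ± 474 against 2192 ± 604 TPM (log2 -1.29), and rps3a had 909 ± 471 against 2048 ± 693 TPM (log2 -1.29). All 78 unigenes of the list with a mean of at least 50 TPM were lower. The mean score over the 99 genes was 7.28 ± 0.67 with food intake and 8.01 ± 0.37 without, lower than the no food intake median in 5 of 6 food intake libraries (two-sided exact permutation p = 0.0325, adjusted p = 0.805 over the lists). The 48 genes became 31, 22 and 29 without food intake 2, 5 or 6 and 19, 22 and 22 without no food intake 2, 4 or 6. That exact permutation p was 0.0628 without food intake 6 and 0.0714 without each of no food intake 2, 4 and 6.

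In the deposited values the ribosomal median was -1.74 in the first batch (score difference -1.27, exact permutation p = 0.0286, the smallest that 3 against 4 allows), and 0.01 in the second (score difference 0.03, exact permutation p = 1). A test of the difference between the batches, over 350 assignments of the labels within batches, gave an exact permutation p of 0.0486, which did not pass over 3 scores (adjusted p = 0.146). After rescaling the score differences were -0.83 and -0.21, of the same sign (exact permutation p = 0.209 for their difference). Smooth muscle and matrix genes had positive medians in the first batch and negative ones in the second. The median over the 99 genes was -0.82 after rescaling, -0.92 with median of ratios scaling and -0.37 with quantile normalization, with 63, 64 and 21 genes lower at unadjusted p under 0.05. Over all 294 unigenes the rescaled values had a median of 0.10 while camera placed the list lower (adjusted p = 0.00923), so median and test differed in sign there.

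**Figure D2:**
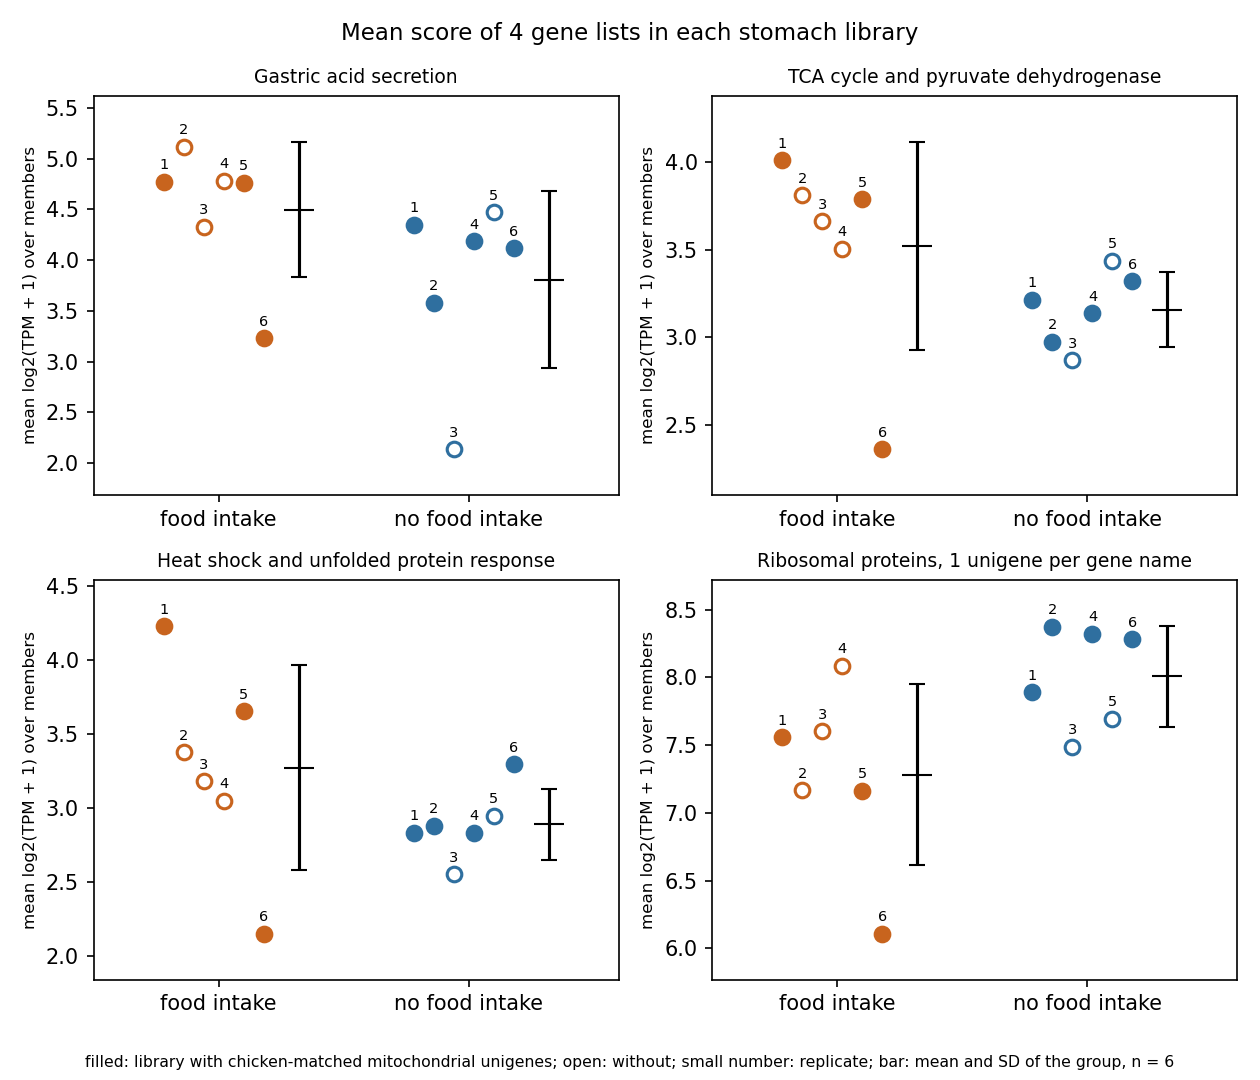
Mean log2(TPM + 1) over the members of 4 gene lists in each library, by feeding group. The ribosomal protein panel uses 1 unigene per gene name (99 genes), and the other panels use all tested unigenes of their list. Points are libraries numbered by replicate, filled where chicken-matched mitochondrial unigenes were above 0; bars give the mean and SD (n = 6); ribosomal protein scores (lower right) average 7.28 with food intake and 8.01 without, and food intake 6, with 64.2% of its TPM on rRNA-like unigenes, is the lowest food intake library in all 4 panels.

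The circadian clock list was the only list that camera placed lower past the threshold, with 20 of 26 unigenes lower and a median of -0.31 (adjusted p = 0.0313; adjusted p = 0.741 with an estimated correlation). PER2 (best match a period 1-like protein) had 1.86 ± 2.94 against 4.52 ± 2.28 TPM (log2 -1.24) and Per1 (best match period 3) 1.68 ± 1.21 against 3.19 ± 1.35 TPM (log2 -0.71), both repressors of the clock, while ARNTL2, a partner of the activator CLOCK, had 3.26 ± 2.47 against 0.580 ± 0.978 TPM (log2 1.35). The medians within the batches were -0.57 and 0.04, and the call was lost without food intake 2, 3 or 5 and without no food intake 1, 5 or 6 (adjusted p up to 0.111). It was also lost with 1 unigene per gene name (camera adjusted p = 0.275), with values summed by name (0.296), at a minimum of 5 TPM (0.249) and without food intake 6 and no food intake 3 together (0.067). The median was -0.16 without food intake 6. The PER2 unigene named here was not the most abundant of its name. With the most abundant unigene per gene name, the lowest log2 change in the clock list was -0.93. The ARNTL2 unigene had 232 bases. Cell cycle genes were higher in 18 of 26 unigenes (median 0.28, camera adjusted p = 0.0313; adjusted p = 0.741 with an estimated correlation), led by pcna, the sliding clamp of DNA replication, with 9.64 ± 5.45 against 3.96 ± 1.45 TPM (log2 0.91). Medians within the batches were 0.11 and 0.43, and this call was lost without food intake 2, 3 or 5 and without no food intake 5 or 6 (adjusted p up to 0.135), with a pseudocount of 0.1 (0.0913), after rescaling (0.0594) and without food intake 6 and no food intake 3 together (0.0512). The median was 0.18, 0.13 and 0.47 without food intake 3, 5 or 6.

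Genes of appetite and gut hormones had both signs, with 16 of 28 unigenes higher and camera adjusted p = 0.325. sst2, a somatostatin precursor and an inhibitor of gastric secretion, had 134.34 ± 73.6 TPM with food intake and 367 ± 204 TPM without (log2 -1.45), and 0 of 6 food intake libraries lay above the no food intake median. Its log2 difference was -2.17 and -0.44 within the batches. Nucb2, the precursor of nesfatin-1, a peptide that reduces food intake, had 15.3 ± 7.83 against 6.62 ± 2.62 TPM (log2 1.01), and TACR1, a tachykinin receptor (best match substance-K receptor), had 3.01 ± 1.52 against 1.203 ± 0.599 TPM (log2 0.82). Galanin (gal) had 25.7 ± 23.2 against 55.5 ± 74.5 TPM, a difference smaller than the spread between fish.

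In the insulin, PI3K and mTOR list 25 of 38 unigenes were lower (median -0.18, camera adjusted p = 0.0814), and 5 were lower and 0 higher at unadjusted p under 0.05. Besides eif4ebp3l these included pten, a phosphatase that opposes PI3K, with 0.522 ± 0.990 against 2.29 ± 0.955 TPM (log2 -1.24), and INSR, the insulin receptor, with 1.99 ± 1.19 against 4.65 ± 1.37 TPM (log2 -0.98). The fasting, FOXO and autophagy list had 34 of 47 unigenes lower (adjusted p = 0.145). Beside sesn1 it held FBXO32, a ubiquitin ligase induced by fasting in muscle, with 0.760 ± 0.607 against 3.898 ± 4.396 TPM (log2 -1.14), and ATG5, an autophagy factor, with 3.84 ± 1.32 against 1.77 ± 1.01 TPM (log2 0.82). The eif4ebp3l, pten (214 bases) and sesn1 unigenes named here were not the most abundant of their names. With the most abundant unigene per gene name, the lowest log2 change was -1.10 in the insulin list and -1.14 in the fasting list. Immediate early genes (14 of 23 lower, adjusted p = 0.94) and the inflammatory response (7 of 9 lower, adjusted p = 0.415) gave no call, although SOCS3, a feedback inhibitor of cytokine signalling, had 8.85 ± 14.4 against 1.62 ± 0.902 TPM.

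Among transporters, peptide and amino acid transport had 14 of 21 unigenes higher (camera adjusted p = 0.0508, 0.741 with an estimated correlation, 0.047 after rescaling and 0.0837 with the batch as a term), with SLC38A3, an amino acid transporter (best match neutral amino acid transporter 5-like), at 12.6 ± 9.15 against 3.99 ± 1.21 TPM (log2 1.12). Ion transport and osmoregulation had 16 of 33 higher (adjusted p = 0.325), with a median of -0.02 although its mean (0.10) and the test were on the higher side. In that list SLC4A4, a sodium bicarbonate cotransporter, had 3.57 ± 2.08 against 1.103 ± 1.19 TPM (log2 1.16) and Slc12a2, a sodium potassium chloride cotransporter, had 5.50 ± 3.26 against 2.01 ± 0.692 TPM (log2 1.003).

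As with the mucous epithelium above, markers of other cell types and tissues did not pass the test between the groups over all 12 libraries with group as the only term. camera gave adjusted p = 0.325 for smooth muscle and motility, 0.24 for extracellular matrix and fibroblasts, 0.325 for neurons and glia, 0.206 for skeletal muscle, 0.08 for phagocytes and granulocytes, 0.94 for T and B lymphocytes, 0.325 for red blood cells, 0.325 for intestinal enterocytes, 0.291 for liver and 0.107 for pancreatic digestive enzymes (0.0492 with the batch as a term, 0.741 with an estimated correlation and group alone). The smooth muscle median was -0.05 although its mean (0.02) and the test were on the higher side, and for lymphocytes median (-0.11) and mean (-0.03) were negative and the test was on the higher side. Smooth muscle and matrix genes had opposite signs in the batches. The smooth muscle median was 0.42 in the first batch and -0.37 in the second (camera adjusted p = 1.19e-10 and 2.55e-06 at the preset correlation), and that of matrix genes 0.58 and -0.74 (camera adjusted p = 1.77e-16 and 1.14e-09). An estimated correlation was not run within batches. In the second batch, smooth muscle scores were 4.24 and 3.61 in no food intake 3 and 5, and 2.89 to 3.86 with food intake. Matrix scores were 3.17 and 2.33 in the same order, and 1.74 to 2.62 with food intake. The second-batch medians of both lists therefore rest in part on no food intake 3. Of the other marker lists, skeletal muscle (camera adjusted p = 0.0239), red blood cells (0.017) and phagocytes (0.0171, lower) passed in the first batch and enterocytes (0.00569) in the second. The red blood cell list had 5 tested unigenes, among them cahz, also in the gastric acid list, and a 214-base HBB with a best match in an ape. The enterocyte members Cdh17 and Vil1 were fragments of 238 and 235 bases with best matches in the rat. ACTA2, smooth muscle actin, had 1013 ± 661 against 1306 ± 1920 TPM overall but a log2 difference of 0.37, with 1.87 and -2.18 within the batches. In the phagocyte list 17 of 19 unigenes were lower (median -0.25), for example LYZ, lysozyme, with 3.84 ± 4.63 against 9.23 ± 8.65 TPM.

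Unigenes matching invertebrates did not separate the feeding groups. The 488 unigenes with an invertebrate best match took 0.391 ± 0.0666% of the TPM with food intake and 0.454 ± 0.138% without (two-sided exact permutation p = 0.377), and 0.414% against 0.435% and 0.368% against 0.492% within the batches. At the level of single unigenes, 3 were above 0 in all 6 food intake libraries and at 0 in all 6 others, and 7 showed the opposite. None of these 10 was annotated, their lengths ran from 201 to 582 bases, and 44 passed when 5 of 6 libraries sufficed. With no counts, a value of 0 does not show absence.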

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

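Of the tests in this part, those of the ribosomal transcripts against the rRNA-like share and the batch, and both tests of the prawn-matched unigenes, were chosen after the result was seen. The batch term and the rescaling were themselves added after seeing the data, also where they are used for the acid and TCA cycle lists. A library was singled out when its gap to the nearest library of its group was large against the range of that group. Chance gives about 1 in 20 groups: over all groups looked at, 6.6 were expected and 22 were found, of which 12 came from food intake 6.

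Food intake 6 lay far from the other food intake libraries in its median log2 value (1.2388), unigenes at 1 TPM or more (28644), share of its top unigene (33.71%) and rRNA-like share (64.23%). Its mean list scores were low for the TCA cycle (2.3641), fatty acid oxidation (1.9308), cholesterol synthesis (1.085), appetite (2.0446), insulin signalling (1.5411), fasting and autophagy (1.6935), enterocytes (1.5634) and ion transport (2.0747). Among no food intake libraries, replicate 1 had 38893 TPM on mitochondrial unigenes of the fish, and replicate 3 had a digestive enzyme score of 8.2078. No food intake 6 had scores of 3.063 for pancreatic enzymes and 2.8651 for skeletal muscle, and no food intake 4 had a log2 value of 3.3964 for plk4. Food intake 4 had an immediate early gene score of 4.3376. Food intake 5 had 222 unigenes above 0 in no other library and 130 TPM on worm-matched unigenes. Prawn-matched mitochondrial unigenes had 338.2 TPM in food intake 4 and 0.3 TPM in no food intake 5.

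Chance could not be excluded for the counts of calls, each taken over splits with the real one included. As many unigenes at unadjusted p came in 26 of 100 splits (real 2518, highest other 4063) and as many lists in 40 of 100 (real 9, highest other 17). As many unigenes detected in 1 group only came in 65 of 462 splits (real 10, highest other 43). For unigenes past adjusted p the real count of 0 is met by 100 of 100 splits whatever they hold (highest other 5), so that count says nothing. The list calls and counts could therefore come from differences between individual fish or libraries that have nothing to do with food.

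The gastric acid and TCA cycle lists were placed higher with food intake by camera (adjusted p = 0.741 for each with an estimated correlation). The tables argue against the rRNA-like share as the whole cause, since the smaller ratio of rescaled to deposited list median was 1.18, and against unequal numbers of each batch in the groups, with a ratio of 1.03 for the acid list once the batch was a term, although the acid median was 0.17 in the first batch (camera adjusted p = 0.0533) and 1.39 in the second. A different share of gland tissue in the samples could account for the acid genes. Their score followed that of the digestive enzymes with a Pearson r of 0.89 after group means were taken out (permutation p = 0.011, adjusted p = 0.044). By rank the relation was weaker, with a Spearman rho of 0.51 (permutation p = 0.12). The rescaled values had a rho of 0.664 (permutation p = 0.028). In the deposited values r was 0.118 without no food intake 3 and food intake 6, whereas in the rescaled values it was 0.826 (permutation p = 0.04, adjusted p = 0.079) and 0.595 without no food intake 3 and food intake 1. Feeding itself stays open beside the gland share.

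Ribosomal protein transcripts were placed lower with food intake by camera in 1 unigene per gene name (adjusted p = 0.778 with an estimated correlation, adjusted permutation p = 0.805). The median kept 0.841 of its size after rescaling and 1.03 with the batch as a term, which argues against the rRNA-like share and unequal batch numbers as the whole cause, although quantile normalization left -0.37 of -0.98 and the score difference was -1.27 in the first batch and 0.03 in the second. A gland share needed a negative r with the acid score, and r was 0.558 (95% interval -0.064 to 0.867), a value that by itself argues against it. That r turned to -0.563 without no food intake 3 and food intake 6, and the rescaled interval (r = 0.12, -0.517 to 0.672) reaches below the bound set in advance, so this share cannot be told apart. Feeding and differences between individual fish stay open too.

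Prawn-matched mitochondrial unigenes stood out in food intake 4. Carry-over from another of the 12 libraries is argued against, because the highest value elsewhere was 0.3 TPM. Food in the stomach could be the source, but only 1 food intake library had more than 1 TPM, so it cannot be told apart from an outside source.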

How the results depend on the processing

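Rescaling, median of ratios, array weights, batches, annotated unigenes and permuted scores were chosen after seeing the data, and the cause of the changes below was not tested. Against 0 unigenes changed, quantile normalization and median of ratios scaling gave 2 each, rescaling and array weights 1 each, unadjusted p 2518, and all other settings 0. Leaving out each library gave 0 to 1. Against 9 lists, an estimated correlation and permuted scores gave 0, leaving out each library 5 to 14, and all other settings 6 to 13. Gastric digestive enzymes reversed within the 7 libraries with chicken-matched unigenes (adjusted p = 0.365 by camera). Of 24 named genes, 10 were left at 5 TPM because 14 were not tested, and at unadjusted p under 0.05 there were 19 within the 7 libraries of the first batch and 12 within the 5 of the second, with 24 of the same sign in both. Each library left out gave 24 to 24. Against 10 unigenes detected in 1 group only, 5 of 6 libraries gave 44, annotated unigenes 0, and leave-one-out 13 to 21. The distance between groups stayed on its side of the threshold in every setting.

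With replicate number as a block, 0 unigenes and 10 lists passed, all 10 higher, and the circadian (0.0611 by camera) and digestive enzyme (0.0505) lists were not called. The numbers do not pair the fish: 1 of 6 pairs correlated above 0.1 (range -0.102 to 0.108), and 0 of 6 libraries matched their own number best. Voom weights and the quasi-likelihood fits were not run because they need counts. A limma fit with a robust prior variance, added after seeing the data, called 0 unigenes (smallest adjusted p = 0.093). Depth is unknown, so its limit on low values could not be given.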

Other observations

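The comparisons of batches in this part were chosen after the result was seen. Unigenes matching a thorny-headed worm (11 unigenes) had 130 TPM in food intake 5 and 0 in the other 11 libraries. Crustacean-matched unigenes had 1816 ± 604.4 TPM with food intake and 2548 ± 1184 TPM without (n = 6 each, two-sided exact permutation p = 0.21), with the highest value, 4805 TPM, in no food intake 3. Of 615 plant-matched unigenes, 544 to 602 were above 0 in the 7 libraries with chicken-matched unigenes and 327 to 461 in the other 5.

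The exact permutation p for a different food effect between batches was 0.354 for the acid score and 0.611 for the TCA cycle score on the deposited values. The small subunit had 32 of 38 ribosomal protein genes lower and the large subunit 45 of 51.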
